A study of Caenorhabditis elegans with 24 samples.

How the data were processed

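Small RNAs were sequenced from whole young adult Caenorhabditis elegans grown at 20 °C on OP50 bacteria. According to the labels, RNA was extracted with TRIzol, small RNAs of about 15 to 30 nt were gel-purified and treated with phosphatase and polynucleotide kinase so that RNAs with a 5′ triphosphate, the form of secondary siRNAs, could be cloned, and the libraries were read on a NextSeq500. There were 24 libraries in 12 groups of 2: wild type (N2), meg-3 meg-4 double mutants (meg-3/4), hrde-1; meg-3 meg-4 triple mutants, and animals of wild-type genotype that descend from outcrossed meg-3/4 animals, at generations F3, F4, F5, F6, F7, F10, F15, F20 and F25. The members of each group are labelled biological replicates, with nothing more said of separate cultures, so the p-values measure the spread between these samples.

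The deposited table gives 1 signal value per gene and library, which the authors made with cutadapt, Bowtie, featureCounts and DESeq2; the versions, the genome build, the annotation and the strand setting are not given in the sources used here. Each value is a whole number of reads divided by 1 factor per library: all 386038 values above 0 gave a whole number within 0.01, and the factors equalled DESeq2's median-of-ratios size factors computed from the recovered reads. The values are therefore called normalized counts. Of the 46726 features listed by WormBase identifier, 46364 matched Ensembl release 115 (WBcel235), which supplied symbols, biotypes and positions, and 362 did not. The build used by the authors may differ.

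The strand that was counted was read from the data. In 28 places a microRNA gene lies opposite a non-coding RNA feature. The non-coding feature was higher in 26 of these, and in 21 of the 21 where it had a mean of at least 10. The summed means were 4.77 normalized counts for the microRNA genes and 418827 for the features opposite them. The values are therefore reads antisense to the annotated gene, which for protein-coding genes is the strand of siRNAs, and the non-coding features opposite microRNA genes hold microRNA reads. Reads of mature microRNAs were therefore not counted at the microRNA genes, and are followed only in the features opposite them, and piRNAs were not measured on their own strand.

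Recovered reads per library ranged from 392785 (F10 replicate 1) to 3420345 (F6 replicate 2). The wild-type libraries held 2926820 and 2884130 reads, the meg-3/4 libraries 2100200 and 2058156, and F4 replicate 2 held 395527. A single read corresponds to 4.99 normalized counts in F4 replicate 2 and 5.47 in F10 replicate 1, against 0.51 to 1.86 in the other 22 libraries. A feature with no reads can lie anywhere up to the level of 3 reads (95% limit, counting error only, since reads copied by PCR are not independent molecules).

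Features with at least 10 normalized counts in at least 2 libraries were kept (8869 features). Differences between groups were tested with limma 3.58.1 (R 4.3.3) with an intensity trend on log2(normalized count + 5), all 12 groups in one fit with 12 residual degrees of freedom. The test was two-sided, with Benjamini-Hochberg adjustment over the kept features at 0.05. Features past that threshold are described as called, higher or lower. The added count of 5 makes the log2 changes of weakly covered features smaller than the ratio of their means. The trend over generations is the slope of log2 level on generation number in the 18 descendant libraries, tested in the same way, and uses no wild-type library. It treats these libraries as independent, although later generations may descend from earlier ones, so its p-values may be too small. The comparison with the mean of the 9 descendant groups uses all of them with equal weight. On simulated data with groups of 2, limma found 74% of features changed by a fold of 2 and 100% of those changed by a fold of 4, and called 2 unchanged features. The trend test found 93% and 100%, and called 6. In both simulations the changed features were drawn only from those with a mean of at least 50 normalized counts. These shares therefore do not cover weaker features.

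Named features were chosen by rule. In each main comparison they are the 10 called features with the largest change in each direction (5 for F3 and for F25) that have a mean of at least 50 normalized counts in the libraries compared and no overlap between the sides. To these were added up to 4 called members of each gene list and, in every case, meg-3, meg-4, hrde-1, sid-1 and rde-11. Of the 26 gene lists, the 21 with at least 3 kept members were tested with camera (limma) at a preset correlation between genes of 0.01, and again with an estimated correlation. Calls were also adjusted over the list alone. The lists were RNAi factors, nuclear RNAi and heritable silencing, Argonautes, germ granule components, the piRNA pathway, histone genes, major sperm protein genes, other sperm genes, oocyte and eggshell genes, mitotic and meiotic germline genes, intestine genes, muscle genes, neuron genes, collagen genes, innate immunity genes, F-box A and B genes, ERGO-1 26G targets, nuclear RNAi targets, ribosomal protein genes, ribosomal RNA genes, microRNA genes, let-7 and lin-4 family microRNAs, mir-35 family microRNAs, piRNA genes, transposon features and the study-named siRNA targets. The comparisons, the tests, the gene lists, the rule for named features and the alternatives were chosen before the data were examined, except where the text says otherwise.

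Features called higher (gained) or lower (lost) in meg-3/4 were followed as sets in the other groups. Because these comparisons share the 2 wild-type or the 2 meg-3/4 libraries, the same medians were computed in 100 simulated data sets in which the followed group did not differ. Part of each set's excess may come from shared controls, and the simulated values show how much chance gives if features vary independently. Noise shared by many features was not simulated and can widen the range of the set medians. As a check chosen after seeing the data, sets were also called against 1 wild-type library and followed against the other, with the spread taken from the other groups.

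Alternatives were an added count of 1 or 20, no filter or a mean of at least 50, equal library totals, quantile normalization, no intensity trend, a fit of only the groups compared, a minimum change of log2 1, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, a replicate block, generation on a log2 scale or as ranks, each library left out in turn and each descendant generation left out in turn. Equal totals of protein-coding features, the omission of the 2 shallowest libraries and the split of the wild-type libraries were added after seeing the data. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9. Phenotypes, other assays of the study and the raw reads were not analysed here.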

Results

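Antisense small RNA levels were measured per gene in 24 libraries of whole young adult C. elegans, 2 in each of 12 groups. MEG-3 and MEG-4 are intrinsically disordered proteins needed to assemble germ granules in the embryo, and HRDE-1 is a nuclear Argonaute that carries siRNAs of the germline from one generation to the next. The groups were wild type, meg-3/4 double mutants, hrde-1; meg-3/4 triple mutants, and animals of wild-type genotype descended from an outcross of meg-3/4, sampled at F3, F4, F5, F6, F7, F10, F15, F20 and F25. Recovered reads ranged from 392785 to 3420345 per library. Of the normalized counts, 61.8% lay antisense to protein-coding genes, 25.1% on non-coding RNA features, 7.79% on pseudogenes and 2.98% on lincRNAs. Among the 8869 features kept there were 7803 protein-coding genes, 408 pseudogenes and 304 non-coding RNAs. A pair of non-coding features that hold microRNA reads, F16A11.6 (opposite mir-71) and K01F9.6 (opposite mir-80), took 13.5% to 29.6% of the counts of a library. Their share was 15.0% and 14.4% in the wild-type libraries and 20.0% or more in both meg-3/4 libraries.

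The genes altered in the mutants were examined first, as a partial check of the labels, since the extent of each deletion is not given in the sources used here. Reads antisense to meg-3 (WBGene00001569, chromosome X) averaged 53.5 ± 15.1 normalized counts in wild type and 7.80 ± 0.0794 in meg-3/4 (SD, n = 2; log2 change −2.17, adjusted p = 4.51e-06), with 42.8 and 64.2 in the wild-type libraries and 7.74 and 7.86 in the meg-3/4 libraries. In the hrde-1; meg-3/4 libraries they were 14.4 and 4.73. Reads antisense to meg-4 (WBGene00016485, chromosome X) were 55.0 and 74.2 in wild type, 12.2 and 3.93 in meg-3/4, and 0.901 and 4.73 in the triple mutant, the first of these from a single read. In the 18 descendant libraries meg-3 ranged from 46.5 to 84.8 and meg-4 from 71.1 to 194.5, above every library of either mutant. For hrde-1 (WBGene00007624, chromosome III) the values were 1351 and 1360 in wild type, 1164 and 1115 in meg-3/4, 1299.6 to 1982 in the descendants, and 628.6 and 599.9 in the triple mutant, the lowest of all 24 libraries.

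The comparison of meg-3/4 with wild type asks which genes gain or lose antisense small RNAs when these germ granule proteins are missing. Small RNAs against the RNAi genes sid-1 and rde-11 rose: sid-1, which encodes the double-stranded RNA channel of systemic RNAi, went from 1233 ± 17.1 to 11609 ± 395.6 normalized counts (log2 3.23, SE 0.131, adjusted p = 7.8e-13), and rde-11, needed for the response to exogenous double-stranded RNA, went from 444.7 ± 11.2 to 6657 ± 358.6 (log2 3.89, SE 0.281, adjusted p = 3.54e-09). B0564.2, whose annotated span on chromosome IV (13107659 to 13111500) follows that of rde-11 (13105200 to 13106927), rose from 89.6 ± 10.4 to 4168 ± 275 (log2 5.47). The largest rise by the log2 change was at the pseudogene C25D7.2 on chromosome V (15037795 to 15038835), from 4.37 ± 4.55 to 3477 ± 252 (log2 8.62, SE 0.384). T03D3.5 rose by 5.03, F26D11.1 by 4.93, tpk-1 (thiamine pyrophosphokinase) by 4.42, the F-box gene fbxa-125 by 4.39, the polo-like kinase gene plk-3 by 4.09 and C15F1.8 by 4.05 on the log2 scale. The pseudogene F07H5.4 rose by 5.25 (SE 0.898) from 6.68 normalized counts. pqn-24 was listed at 0 in both wild-type libraries, where 3 reads would be 1.74 and 1.75 normalized counts, and at 146.2 ± 12.7 in meg-3/4.

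The largest loss in meg-3/4 was at trp-4, a mechanosensory channel gene, which fell from 554.6 ± 10.02 to 3.56 ± 1.91 normalized counts (log2 −6.05, SE 0.198, n = 2, adjusted p = 6.34e-14 from limma). dyf-3, needed to build sensory cilia, fell from 446.4 to 5.71, and ckk-1, a calmodulin-dependent kinase kinase gene, from 642.5 to 11.5. rimb-1, which encodes a RIM-binding protein of the presynaptic active zone, fell from 223.2 to 1.54. The Krüppel-like factor gene klf-1 fell from 764.6 to 8.97, mnp-1 from 497.9 to 7.61, the collagen gene col-111 from 276.3 to 3.13, Y38F2AR.12 from 422.7 to 4.11, Y69A2AR.31 from 491.0 to 7.92 and ZK973.8 from 477.2 to 9.64. The log2 changes of these 9 other genes ranged from −5.10 to −5.80, and the values near 0 rest on few reads.

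Among the gene lists, more F-box genes lost than gained small RNAs in meg-3/4. Of 102 measured F-box A and B genes, which encode substrate adaptors of ubiquitin ligases, 58 fell, 5 rose and 39 were not called (adjusted over the list alone, 65 and 5). Examples were fbxa-184 (log2 −3.56), fbxb-22 (181.7 to 18.98 normalized counts) and fbxb-24 (315.1 to 35.7), against the rise of fbxa-125. The list passed camera (median −1.02, adjusted p = 1.16e-08), also with an estimated correlation (adjusted p = 0.0171), and most of its called members were lower under every scaling tried. All 4 measured ribosomal RNA genes rose (4 adjusted over the list alone, 3 with equal library totals). One of them, rrn-2.1 (log2 0.80), lost its call without wild-type replicate 1 (adjusted p = 0.19) or 2 (0.0932) and without meg-3/4 replicate 1 (0.15) or 2 (0.109). rrn-3.1 went from 2595 to 5994, and the log2 changes of the 2 copies of rrn-1.1 were 1.74 (WBGene00004512) and 1.82 (WBGene00004513). The 3 features annotated on the strand opposite ribosomal RNA genes rose as well, from a summed 10830 ± 3145 normalized counts in wild type to 42950 ± 14790 in meg-3/4 (SD, n = 2, untested). That list passed camera (adjusted p = 0.000404) but not with an estimated correlation (adjusted p = 0.446 with an estimated correlation). Of 75 ribosomal protein genes 15 fell and 0 rose (15 and 0 adjusted over the list alone), among them rps-4 (123.5 to 37.2) and rps-21 (log2 −1.50). Of 21 collagen genes 8 fell and 6 rose, with the largest losses at col-111, col-38 (−3.63) and col-155 (−2.06). Of 10 neuron genes 3 fell, including ida-1 (−1.80) and egl-21 (−1.68). The ribosomal protein, collagen and neuron lists did not pass camera (adjusted p = 0.121, 0.781 and 0.819). Among all 8869 kept features 1564 fell and 734 rose. Without wild-type replicate 2 the F-box counts were 35 lower and 3 higher, and without meg-3/4 replicate 1 they were 43 and 3. The ribosomal protein count was 7 without wild-type replicate 1 and 9 without meg-3/4 replicate 1. Collagen genes numbered 5 lower and 3 higher, 7 and 3, and 5 and 2 without wild-type replicate 1, wild-type replicate 2 and meg-3/4 replicate 1. Where no other pair of counts is given, here and in the other comparisons, adjustment over the list alone gave equal counts.

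Lists of small RNA pathway genes held calls in both directions in meg-3/4. Of 20 RNAi factors 3 rose and 1 fell (3 and 1 adjusted over the list alone), with the largest changes at sid-1 and rde-11. These genes, entered as the study-named siRNA targets because the study is known for them, both rose, which is not independent evidence. Of 13 nuclear RNAi and heritable silencing genes 2 rose and 2 fell. They included hpl-1, a heterochromatin protein 1 gene (−1.46), nrde-1 (−0.60) and set-25, a histone H3 lysine 9 methyltransferase gene (0.59, no longer called with equal library totals). Of 25 germ granule components 2 fell, the mutated meg-3 and meg-4. Of 19 Argonautes 1 fell (0 adjusted over the list alone), of 15 piRNA pathway genes 2 rose and 1 fell (4 and 1 alone), and of 11 ERGO-1 26G targets 3 rose and 4 fell, W04B5.1 rising by 0.85. Of 6 nuclear RNAi targets 2 fell, both named F07B7.2 (WBGene00021107, −3.12, and WBGene00017186, −3.04), and bath-45 rose (0.38). Its call was lost without wild-type replicate 1 (adjusted p = 0.0736) or 2 (0.0854) or meg-3/4 replicate 1 (0.113), and its direction turned with quantile normalization (−0.31, called lower). Leaving out any of the 4 libraries left 2 or 3 RNAi factors higher and 0 lower, 1 nuclear RNAi gene higher and 2 lower, 2 ERGO-1 targets higher and 2 lower, and 0 Argonautes lower. The piRNA pathway counts were 0 and 1 without wild-type replicate 1 and 0 and 0 without meg-3/4 replicate 2. With equal library totals, where the median of all features is lower, 2 RNAi factors rose and 8 fell, 0 and 4 piRNA pathway genes, and 0 and 9 germ granule components.

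Germline and somatic marker lists did not pass camera in meg-3/4, and the direction of their calls differed from list to list. Of 44 histone genes 5 rose and 4 fell (3 and 3 adjusted over the list alone), with his-38 at −1.34 and his-37 at −1.23, while with equal library totals 0 rose and 8 fell. Of 12 sperm genes other than msp 3 fell, spe-15 (−2.20), spe-41 (−1.70) and spe-6 (−1.64), and 1 rose. That list's median was 0.06 while its mean was −0.31 and its test pointed down without passing. Of 23 mitotic and meiotic germline genes 2 rose and 1 fell (1 and 1 alone), with the Notch receptor gene glp-1 at −0.66. Of 21 oocyte and eggshell genes chs-1 and puf-5 fell, of 6 intestine genes vit-3 rose and of 8 muscle genes unc-54 fell (0 alone). chs-1 lost its call without any of the 4 libraries (adjusted p from 0.0606 to 0.117), puf-5 without wild-type replicate 1 (0.172) or meg-3/4 replicate 1 (0.0738) or 2 (0.0882), vit-3 without wild-type replicate 1 (0.222) or meg-3/4 replicate 1 (0.161) or 2 (0.0553), and unc-54 without wild-type replicate 1 (0.138) or 2 (0.11) or meg-3/4 replicate 2 (0.409). Histone genes rising numbered 3, 1, 0 and 3 without wild-type replicates 1 and 2 and meg-3/4 replicates 1 and 2, with 3 falling each time, and 1 germline gene rose in each case. The sperm gene that rose lost its call without wild-type replicate 1 or 2. limma called 0 of 7 major sperm protein genes (0 at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2), 0 of 8 microRNA genes (1 unadjusted, 1 by edgeR and 0 by DESeq2) and 0 of the 1 innate immunity gene measured (0 by each). Of 90 piRNA genes kept from 15363 listed, 2 rose and 1 fell (0 alone), and 0 fell without any of the 4 libraries, with 1, 0, 0 and 5 rising in the order given. No gene of the let-7, lin-4 or mir-35 families was kept. Features on the opposite strand of lin-4 (F59G1.10, log2 0.36) and of mir-42 of the mir-35 family (ZK930.12, 1.29) were kept. ZK930.12 also lies opposite mir-43, so its reads cannot be assigned to mir-42 alone. Neither feature was called, and both were chosen after the data were seen. No transposon feature was listed.

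In all, 734 features were higher and 1564 lower in meg-3/4 (68.1% lower), of which 301 and 1112 changed at least by log2 1. By biotype the counts were 570 higher and 1408 lower among protein-coding genes, 50 and 117 among pseudogenes, and 78 and 8 among non-coding RNAs. The split depends on the scaling. With equal library totals the median of all features moved by −0.33 and the counts were 294 and 2659 (90.0% lower), and with quantile normalization the median moved by 0.13 and they were 1390 and 1337 (49.0% lower). The higher count was 410 without wild-type replicate 1, 429 without wild-type replicate 2 and 433 without meg-3/4 replicate 1.

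**Figure D1:**
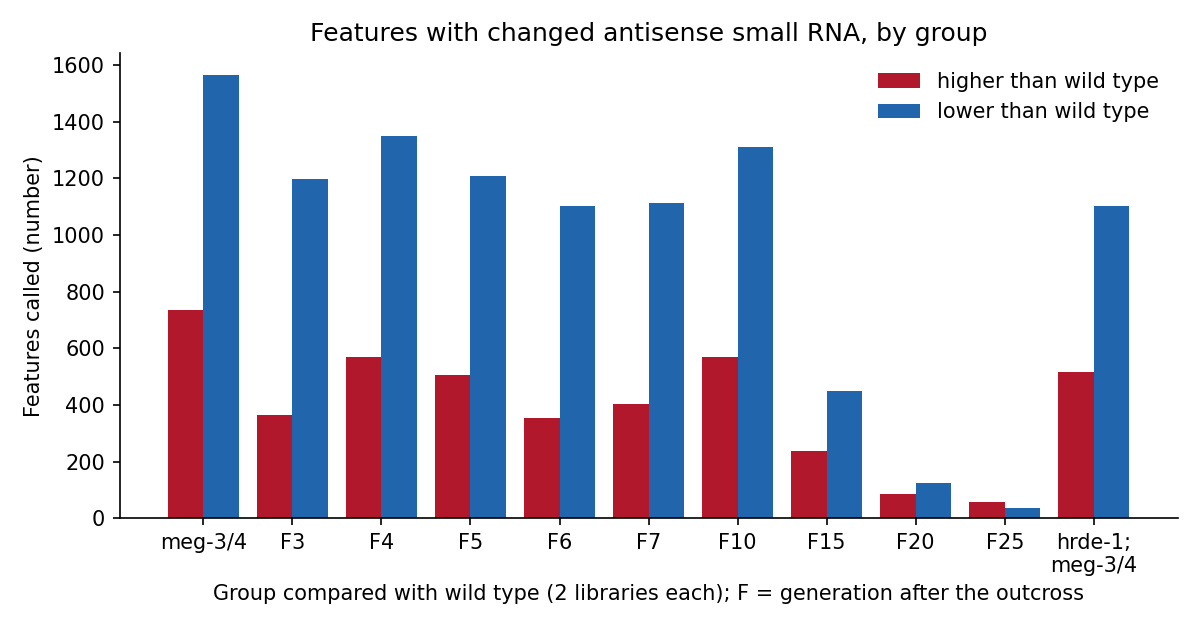
Number of features called higher (red) and lower (blue) than wild type by limma in each group of 2 libraries, at an adjusted p under 0.05. The counts go from 734 higher and 1564 lower in meg-3/4 to 56 and 37 at F25, and were 517 and 1101 in hrde-1; meg-3/4. F4 and F10 each include a library with few reads, and their larger counts are not secure.

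The descendants carry wild-type meg-3 and meg-4, so comparing each generation with wild type asks how far the altered small RNAs outlast the mutation. Small RNAs against sid-1 remained high for many generations: 8376 ± 103.9 normalized counts at F3 (log2 2.76), 4651 ± 644 at F10 (1.90) and 1316 ± 242 at F25 (0.08, adjusted p = 0.898). The change was 2.64, 2.56, 2.50 and 2.38 at F4, F5, F6 and F7, 1.03 at F15 (adjusted p = 8.85e-05) and 0.52 at F20 (adjusted p = 0.0409, limma). The call at F20 was lost without either wild-type library (adjusted p = 0.225 and 0.214) and without F20 replicate 1 (0.12) or 2 (0.194). Against rde-11 the level was 3388 ± 655.6 at F3 (2.90), 1002 ± 388.7 at F10 (1.11, adjusted p = 0.00842) and 464 ± 2.41 at F25 (0.06, adjusted p = 0.973). For rde-11 the changes at F15 (0.62, adjusted p = 0.216) and F20 (0.33) did not pass the test, and the call at F10 was lost without wild-type replicate 2 (adjusted p = 0.0582) or F10 replicate 2 (0.104).

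**Figure D2:**
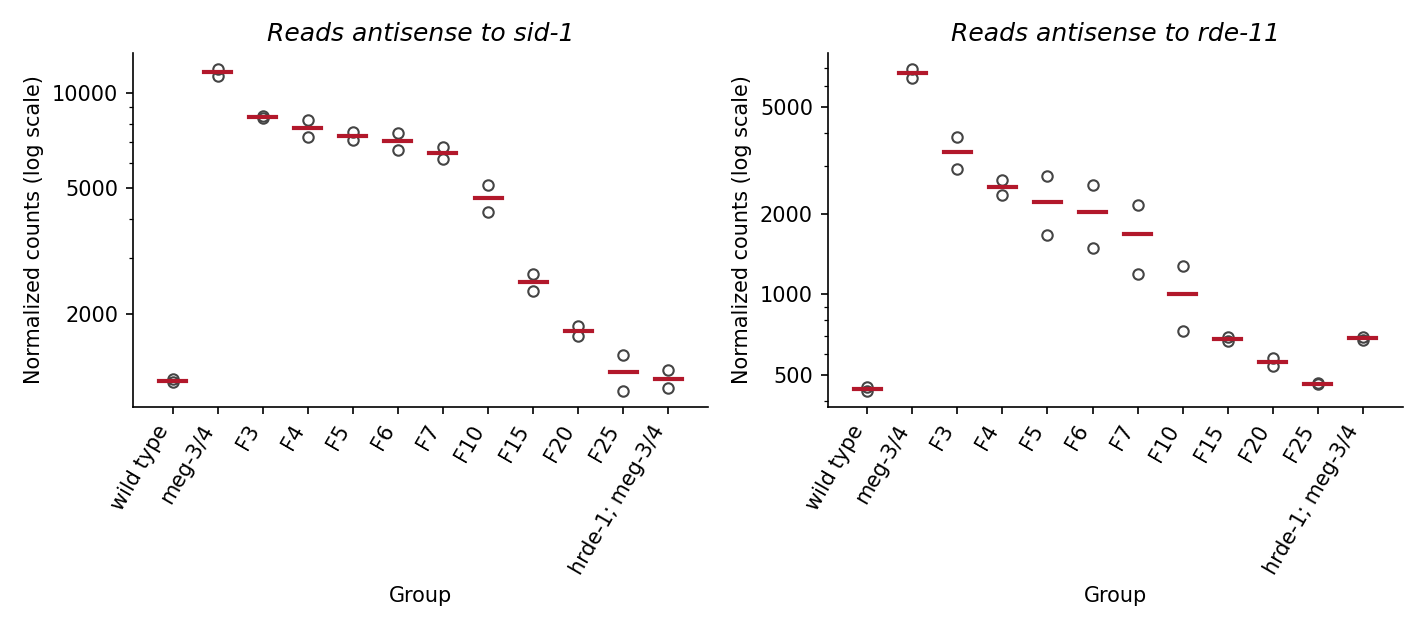
Normalized counts of reads antisense to sid-1 (left) and rde-11 (right), on log scales, in each of the 2 libraries (circles) of the 12 groups, with group means (red bars). The sid-1 libraries go from 11889 and 11329 in meg-3/4 to 1145 and 1488 at F25, beside 1221 and 1246 in wild type.

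Averaged over the 9 descendant groups, the pseudogene C25D7.2 was the feature with the largest rise over wild type (log2 6.48, SE 0.286), at 980.9 ± 246 normalized counts at F3 and 280.5 ± 214 at F25 against 4.37 ± 4.55 in wild type. The pseudogene F59A1.9 stood at 2005 at F3, 2149 at F10 and 1850 ± 278 at F25 against 302.0 ± 5.94 in wild type and 2598 in meg-3/4 (log2 2.71, SE 0.0968). plk-3 stood at 4683 at F3, 3271 at F10 and 1098 ± 674 at F25, against 387.7 ± 4.17 in wild type. F26D11.1 (3.19), T03D3.5 (3.02), Y38C1AB.5 (2.98), ZC190.8 (2.93) and C15F1.8 (2.82) were also among the 10 with the largest rise. Small RNAs against xdh-1, a xanthine dehydrogenase gene (3.71), were at 3.20 in wild type, 20.5 at F3 and 228.5 at F25, and those against the aldolase gene aldo-1 (3.10) at 10.5, 78.7 and 262.8. Levels of ZC190.8 and aldo-1 differed between replicates 1 and 2 of the descendants, as given below.

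The largest losses averaged over the descendants were at ndx-2, a nudix hydrolase gene (log2 −3.53), the transcription factor gene hlh-11 (−3.40) and jip-1, a JNK-interacting scaffold gene (−3.36). hlh-11 was at 649.5 normalized counts in wild type, 24.1 in meg-3/4, 73.1 at F3 and 259.8 at F25. K10D2.8 (−3.25) was at 349.6 ± 16.3 in wild type, 9.21 at F3 and 71.2 at F25. Small RNAs against xol-1, the master switch of sex determination (−2.54), went from 286.9 in wild type to 28.7 in meg-3/4, 30.8 at F3 and 157.3 at F25. unc-10, which encodes the presynaptic protein RIM (−2.46), was at 382.6 in wild type, 41.4 at F3 and 273.6 at F25. ZC404.2 (−2.67), elmd-1 (−2.55), Y69A2AR.31 (−2.51) and F31E9.6 (−2.51) complete the 10.

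At F3 the features that rose most were C25D7.2 (6.78), F26D11.1 (5.09), B0564.2 (4.84), T03D3.5 (4.33) and Y94H6A.7 (3.67), and those that fell most were the peroxin gene prx-11 (241.8 ± 97.6 to 1.72 normalized counts), ndx-2 (−5.14), Y65B4BL.7 (190.0 to 1.01), K10D2.8 (−4.65) and E01G4.5 (1730 to 83.6). At F25 the largest rises were at xdh-1 (4.79, adjusted p = 6.2e-07), C25D7.2 (4.78), aldo-1 (4.01), idpp-2 (2.62) and F59A1.9 (2.59, adjusted p = 4.73e-10). The largest loss at F25, at Y34D9A.8 (−2.94), lost its call without each of the 4 libraries compared (adjusted p from 0.0697 to 0.17). Of the others Y65B4BL.7 (−2.27) and K10D2.8 (−2.22, adjusted p = 2.68e-05) kept their calls with each library left out, while jip-1 (−2.42) lost it without F25 replicate 2 (adjusted p = 0.0786) or wild-type replicate 2 (0.0655), and prx-11 (−2.18) without F25 replicate 1 (0.0601) or wild-type replicate 1 (0.103). Between F3 and F25 themselves 812 features were higher and 285 lower at F25. That total of 1097 was 731 without F3 replicate 1, 685 without F3 replicate 2 and 485 without F25 replicate 1.

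Averaged over the descendants, 36 of 102 F-box genes were lower, 9 higher and 57 not called (46 and 12 adjusted over the list alone). fbxb-51 (−1.71) and fbxb-91 (−1.63) fell, while fbxa-125 (1.89) and fbxa-136 (1.68) rose (camera adjusted p = 0.047, and adjusted p = 0.465 with an estimated correlation). Of 75 ribosomal protein genes 14 fell and 0 rose (14 and 0 alone), with rps-4 at −1.32 and rpl-34 at −1.31 (camera adjusted p = 0.047, and adjusted p = 0.472 with an estimated correlation). Of 44 histone genes 10 fell and 1 rose (10 and 1 alone), with his-38 at −1.46 and his-37 at −1.22. Of 20 RNAi factors 3 rose and 2 fell, of 13 nuclear RNAi genes 2 rose and 1 fell (2 and 2 alone), hpl-1 again lower (−1.24), and of 15 piRNA pathway genes only tofu-2 fell (−1.001). The germ granule list passed camera (adjusted p = 0.047, and adjusted p = 0.465 with an estimated correlation), with 4 of 25 members higher and 1 lower (0 and 1 with equal library totals). Among them meg-4 (0.77, adjusted p = 0.0236), deps-1 (0.34) and pgl-2 (−0.72) lost their calls without wild-type replicate 1 (adjusted p = 0.336, 0.424 and 0.121) or wild-type replicate 2 (0.0762, 0.113 and 0.0914), and the counts were then 1 and 0, and 0 and 0. Without wild-type replicate 1 and without replicate 2, in that order, 21 and 20 F-box genes were lower and 4 and 5 higher, 4 and 6 ribosomal protein genes and 3 and 5 histone genes were lower, and in each case 2 RNAi factors were higher and 0 lower and 1 nuclear RNAi gene went each way. Among the descendant libraries, 1 RNAi factor was lower without F3, F5, F7 or F25 replicate 2 or F6 replicate 1, 2 nuclear RNAi genes without F4 replicate 2 or F10 replicate 1, 2 germ granule members without F4 replicate 1, and 2 piRNA pathway genes without F4, F20 or F25 replicate 1 or F10 replicate 1 or 2.

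Against wild type the counts were 364 higher and 1196 lower at F3, 570 and 1348 at F4, 506 and 1207 at F5, 354 and 1101 at F6, 403 and 1114 at F7, 571 and 1309 at F10, 239 and 449 at F15, 87 and 126 at F20 and 56 and 37 at F25, and for the mean of the 9 groups 557 and 1346. F4 and F10, with the largest totals, each include a library with few reads (395527 and 392785). By DESeq2 the counts were 425 higher and 910 lower at F4, 433 and 1093 at F7, and 397 and 697 at F10. The larger totals at F4 and F10 are therefore not secure. The share lower was 76.7, 70.3, 70.5, 75.7, 73.4, 69.6, 65.3, 59.2 and 39.8% from F3 to F25 and 70.7% for the mean. With equal library totals it was 87.9, 86.0, 83.6, 88.1, 88.6, 91.5, 89.5, 91.8 and 66.7%, and 90.0% for the mean. With quantile normalization it was 61.3, 54.9, 58.9, 63.2, 63.4 and 57.2% from F3 to F10, and 57.1% for the mean. A fit of only the groups compared called 38 higher and 55 lower at F25 (59.1% lower), and no filter 68 and 68 at F20.

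The totals lean on single libraries. Without wild-type replicate 1 and without wild-type replicate 2, in that order, they were 963 and 912 at F3, 1111 and 1056 at F4, 1001 and 924 at F5, 835 and 787 at F6, 804 and 803 at F7, 1022 and 982 at F10, 241 and 226 at F15, 62 and 61 at F20 and 49 and 48 at F25. Without descendant replicate 1 and without replicate 2 they were 1028 and 1033 at F3, 1084 and 1041 at F5, 855 and 851 at F6, 863 and 895 at F7, 315 and 239 at F15 and 83 and 101 at F20, and without replicate 2 alone 1237 at F4 and 56 at F25. The counts of 557 and 1346 for the mean were 184 and 653 without wild-type replicate 1, and 173 and 592 without wild-type replicate 2.

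The 734 features gained and the 1564 lost in meg-3/4 were followed as sets. The gained set had a median log2 change from wild type of 0.39 at F3 (SD 0.00109, n = 2), 48.8% of its meg-3/4 median, and of 0.38, 0.37, 0.34, 0.34, 0.29, 0.26, 0.20 and 0.11 (SD 0.07 at F25, 14.2%) at the later generations sampled. The lost set went from −0.94 at F3 (SD 0.0136, 71.8% of its meg-3/4 median) through −0.90, −0.90, −0.87, −0.83, −0.76, −0.53 and −0.43 to −0.24 at F25 (SD 0.164, 18.02%). At F3, 245 of the gained features were called higher, against 30.1 if the calls were independent, and 954 of the lost features were called lower, against 210.9. At F25 these numbers were 21 against 4.64 and 27 against 6.53, while calls in the opposite direction, 9 gained features lower against 3.06 and 19 lost features higher against 9.88, also exceeded the numbers of independent calls (2 and 22 opposite calls at F3). In simulated data with no change in the followed group, F3 medians of the gained set ran from 0.0480 to 0.0859, and the median of the lost set was −0.04. At F25, 69.9% of gained and 78.4% of lost features still lay on the same side as in meg-3/4, against 63.7% and 57.3% in the simulated data. The F25 libraries lay further apart than the simulated F25 medians, which ran from 0.0494 to 0.0828 (gained) and from −0.0660 to −0.0220 (lost). Simulated features varied independently, so these values may understate chance. Without F25 replicate 2 the F25 medians were 0.06 (gained) and −0.13 (lost), and without F25 replicate 1 they were 0.16 and −0.36. With the sets called against 1 wild-type library and followed against the other, a check chosen after the data were seen, the F3 medians were 0.45 and 0.47 (42.6% of the meg-3/4 median each way) for the gained and −1.05 and −1.03 (66.2% and 67.8%) for the lost set, and those at F25 0.08 and 0.12 (7.41% and 10.73%) and −0.24 and −0.22 (15.1% and 14.4%). One of the F25 libraries lay within the simulated range for the gained set, as the plot of the sets by generation shows.

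**Figure D3:**
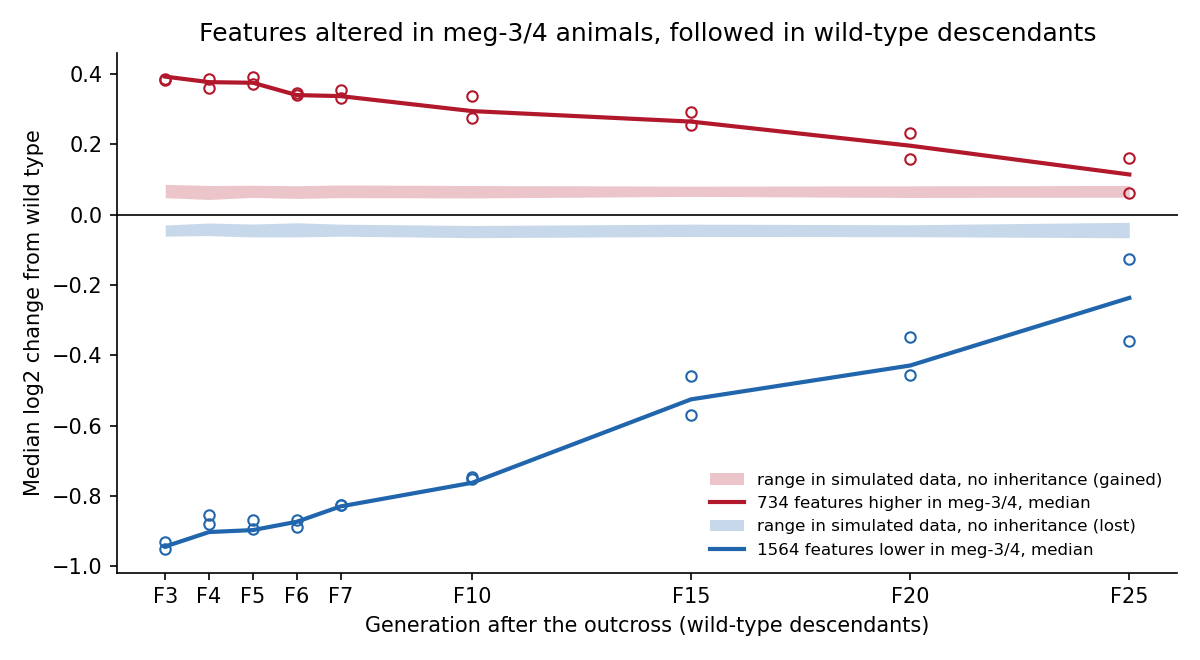
Median log2 change from wild type, by generation, of the 734 features higher (red) and 1564 lower (blue) in meg-3/4. Lines are the medians of the group's change, circles those of each library, and bands the range in 100 simulated data sets with no change. Features varied independently in the simulation, so the bands may be too narrow. The medians go from 0.39 and −0.94 at F3 to 0.11 and −0.24 at F25.

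The trend within the descendants, which uses no wild-type library, asks which small RNAs change from F3 to F25. Small RNAs against B0564.2 fell fastest, by 0.27 on the log2 scale per generation (SE 0.015, adjusted p = 2.31e-11), from 2707 normalized counts at F3 to 63.9 at F25. F26D11.1 went from 1886 to 62.6, T03D3.5 from 3061 to 285.9, Y94H6A.7 from 735.6 to 41.4, Y92H12BL.5 from 1334 to 99.2, F41C3.8 from 121.3 to 7.42 and fbxa-125 from 180.2 to 15.7. The slopes of sid-1 (SE 0.00495, adjusted p = 6.7e-14) and of rde-11 (adjusted p = 6.72e-08) were both −0.13. The histone gene his-47 (WBGene00001921, −0.14) and Y48G1BL.5 (−0.14) also fell. ndx-2 rose fastest, by 0.21 per generation (SE 0.0202, adjusted p = 1.31e-07), from 6.03 to 147.1. Genes that had lost small RNAs in meg-3/4 rose as well: dyf-3 went from 25.4 to 429.5, ckk-1 from 25.6 to 448.1, Y38F2AR.12 from 38.2 to 463.3 and klf-1 from 51.3 to 450.6. hpo-39 (35.9 to 394.6), K07A1.3 (10.9 to 195.0), idpp-2 (15.0 to 271.3), fbxa-61 (13.2 to 220.3) and ZC239.21 (0.15) complete the 10 fastest.

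More F-box genes rose than fell over the generations: 54 of 102 had a rising trend, 4 a falling one and 44 none (61 and 5 adjusted over the list alone), with fbxb-91 going from 26.8 to 162.8 normalized counts (camera adjusted p = 2e-08, and adjusted p = 0.0702 with an estimated correlation). With a mean of at least 50, 13 of 35 rose and 3 fell. The median slope was then 0.010, against 0.034 for the 102. Of 11 ERGO-1 26G targets 8 rose and 0 fell (8 and 0 alone). E01G4.5 went from 83.6 to 1419, Y17D7B.4 from 207.4 to 1358, W04B5.2 from 362.6 to 1409 and E01G4.7 from 251.4 to 1090 (camera adjusted p = 0.00243, and adjusted p = 0.457 with an estimated correlation). All 4 ribosomal RNA genes fell (4 alone, camera adjusted p = 0.00462, and adjusted p = 0.457 with an estimated correlation), while the features opposite them summed to 17180 ± 3275 normalized counts at F3 and 24650 ± 3921 at F25 (untested). The trend of rrn-2.1 lost its call without F3 replicate 1 (adjusted p = 0.0624) or 2 (0.0729), F4 replicate 1 (0.0509), F5 replicate 2 (0.0517), F6 replicate 2 (0.0502) or F25 replicate 1 (0.132). Of 44 histone genes 10 fell and 4 rose (13 and 6 alone), of 75 ribosomal protein genes 7 rose and 1 fell (4 and 0 alone, 2 and 1 with equal library totals), of 20 RNAi factors 3 fell and 2 rose, and of 21 collagen genes 3 rose, col-38 by 0.09 and col-111 by 0.07 per generation, and 2 fell. Without F25 replicate 1 only 2 ribosomal protein genes rose, and the 1 that fell kept its call only without F4 replicate 2, F5 replicate 1 or 2, F6 replicate 1, F7 replicate 2, F10 replicate 1 or F15 replicate 2. The rising RNAi factors stayed at 2 only without F10 replicate 1 or 2 or F15 replicate 2 and were 0 or 1 without any other library.

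In all 1224 features had a rising and 666 a falling trend (35.2% falling), and 1054 and 970 with quantile normalization (47.9% falling) and 594 and 605 with a mean of at least 50 (50.5% falling). Without F25 replicate 1 the falling count was 370. Of the 1564 features lost in meg-3/4, 901 had a rising and 52 a falling trend. Of the 734 gained features 244 had a falling and 12 a rising trend, against 370 and 311 of the 6571 other features.

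The comparison of hrde-1; meg-3/4 with meg-3/4 asks which small RNAs change when HRDE-1 is lost as well. No group lacked HRDE-1 alone. A need for HRDE-1 in the meg-3/4 alteration therefore cannot be told from a general effect of losing HRDE-1. In the triple mutant the small RNAs against sid-1 and rde-11 fell: sid-1 was at 1252 ± 114.6 normalized counts (log2 −3.21 against meg-3/4, adjusted p = 4.68e-13; 0.02 against wild type, adjusted p = 0.954) and rde-11 at 686.1 ± 11.5 (−3.27 against meg-3/4, adjusted p = 2.97e-08; 0.62 against wild type, adjusted p = 0.151). B0564.2 fell from 4168 to 106.6, close to its wild-type level of 89.6. Other features fell below wild type: pbo-1 went from 953.3 in meg-3/4 to 15.5, against 165.4 in wild type, the ether lipid synthesis gene ads-1 from 1139 to 19.6 (462.2 in wild type), the DnaJ chaperone gene dnj-24 from 2069 to 50.9 (287.8 in wild type), and lido-18 from 1857 ± 208 to 56.2 ± 5.87 (1480 ± 1.10 in wild type). WBGene00044400, which the annotation does not hold, fell most (−6.49, 1429 ± 139 to 11.09), followed by Y53F4B.17 (690.2 to 5.69) and Y53F4B.16 (1812 to 26.3). F07H5.4 (−5.17) and F27C1.18 (497.7 to 11.7) also fell.

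Small RNAs against other genes rose in the triple mutant. T25B9.8 rose from 17.3 to 1346 ± 407 normalized counts (log2 5.89, SE 0.366, n = 2, adjusted p = 2.74e-10), hpo-38 from 13.6 to 1055 ± 94.9, Y54F10BM.13 from 26.2 to 1279, F41G4.5 from 8.91 to 567.5 and R102.4 from 9.40 to 559.4. The wild-type levels of T25B9.8 and hpo-38 were 35.8 and 41.5. T11F9.19 (2.77 to 284.0), ZC15.1 (1.11 to 217.0) and the ground-like gene grl-18 (2.03 to 271.2, and 2.03 in wild type) had few reads in meg-3/4. elmd-1 rose from 14.2 to 846.8 ± 76 (212.0 in wild type), and K10D2.8 from 6.69 to 376.5 ± 11.61, beside 349.6 in wild type.

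The gained set changed by a median of −0.45 (SD 0.00637) from meg-3/4 to the triple mutant, with 320 of its 734 features called lower and 18 higher, and the lost set by 0.54 (SD 0.0259), with 613 of 1564 called higher and 140 lower. Without meg-3/4 replicate 2 the gained median was −0.79. Simulated data with no change gave −0.06 and 0.05. Against wild type the gained set stood at 0.26 and the lost set at −0.68 in the triple mutant, where 718 of the lost features were still called lower.

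No list passed camera in this comparison, with a preset or an estimated correlation (6 and 0 of 21 unadjusted). F-box genes went both ways, 20 of 102 rising and 19 falling (23 and 21 adjusted over the list alone): fbxa-60 rose from 31.6 to 678.9 normalized counts, fbxa-10 from 216.4 to 1778 and fbxb-22 from 18.98 to 207.7, while fbxa-136 fell from 332.9 to 23.6. Of 44 histone genes 8 rose and 1 fell (8 and 1 alone). his-38 went from 22.9 to 82.6 and his-67 rose by 1.49, and his-24, a linker histone gene, fell from 5963 to 2848. Of 6 nuclear RNAi targets R03D7.2 rose (69.4 to 444.3), and C38D9.2 (1207 to 210.4) and bath-45 (6858 to 2930) fell. Of 20 RNAi factors 5 fell and 1 rose (2 and 2 with equal library totals), and of 13 nuclear RNAi genes hrde-1 itself (−0.89) and set-25 (−0.67, not called with equal library totals) fell and nrde-2 (0.47) rose. Of 11 ERGO-1 26G targets 5 fell and 0 rose (1 and 0 with equal library totals), W04B5.1 by −0.65. Of 75 ribosomal protein genes 8 rose and 0 fell (4 and 0 alone), rps-4 by 1.47, and of 21 oocyte and eggshell genes 3 rose, puf-5 by 0.66. Without meg-3/4 replicates 1 and 2 and hrde-1; meg-3/4 replicates 1 and 2, in that order, 4, 5, 4 and 3 histone genes and 4, 3, 3 and 3 ribosomal protein genes rose, and 3, 3, 3 and 4 RNAi factors fell with 0 rising. Without meg-3/4 replicate 1 the F-box counts were 15 rising and 12 falling. The oocyte and eggshell count was 1 without meg-3/4 replicate 1 or hrde-1; meg-3/4 replicate 2, and the ERGO-1 count 3 without these or hrde-1; meg-3/4 replicate 1. All 4 ribosomal RNA genes fell, beside the features opposite them (42950 to 24320 normalized counts), but 0 were called with equal library totals (0 unadjusted) and 1 with quantile normalization. Their calls were all lost without meg-3/4 replicate 1 (adjusted p from 0.15 to 0.279), hrde-1; meg-3/4 replicate 1 (0.0618 to 0.296) or 2 (0.0779 to 0.267), and 3 of them without meg-3/4 replicate 2 (0.0791 to 0.128).

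In all 938 features were higher and 765 lower in hrde-1; meg-3/4 than in meg-3/4 (44.9% lower), and 1408 and 439 with equal library totals (23.8% lower, median shift 0.21). With equal protein-coding totals the counts were 1224 and 600 (32.9% lower), and with a mean of at least 50 the balance turned, with 508 higher and 646 lower (55.98% lower). The higher count was 616 without hrde-1; meg-3/4 replicate 1. Against wild type 517 were higher and 1101 lower (68.0% lower), and 939 and 996 with quantile normalization (51.5% lower). In that comparison 44 of 102 F-box genes were lower and 6 higher (48 and 8 alone, camera adjusted p = 1.47e-06, also past the test with an estimated correlation, adjusted p = 0.0483). Histone genes, 10 of 44 higher and 2 lower (12 and 3 alone), passed camera (adjusted p = 0.00161, and adjusted p = 0.355 with an estimated correlation), as did oocyte and eggshell genes, 4 of 21 higher (0.0434, and adjusted p = 0.587 with an estimated correlation), and ribosomal RNA genes, 2 of 4 higher (3 alone, 0.0288, and adjusted p = 0.587 with an estimated correlation). Without wild-type replicates 1 and 2 and hrde-1; meg-3/4 replicates 1 and 2, in that order, 7, 4, 4 and 3 histone genes and 1, 1, 1 and 2 oocyte and eggshell genes were higher, and 1 histone gene was lower without the first or the last of these.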

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

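The comparison of F25 with F3 and the count over other orders of the generations were planned, and the tests of the features that differ from wild type at F25 were chosen only after the results were seen. Groups of 2 libraries are too small to test for a single library far from the others.

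The change from wild type differed between generations. Tested directly between F25 and F3, 812 features were higher and 285 lower at F25, a total of 1097 that was 731 without F3 replicate 1, 685 without F3 replicate 2 and 485 without F25 replicate 1. Of the features named at F3 or F25, small RNAs against B0564.2 (log2 −5.29), F26D11.1 (−4.83), Y94H6A.7 (−3.92), T03D3.5 (−3.49), rde-11 (−2.84), sid-1 (−2.68) and C25D7.2 (−2.003) were lower at F25. Those against E01G4.5 (4.19), ndx-2 (3.76), idpp-2 (3.61), xdh-1 (3.22), prx-11 (2.96), Y65B4BL.7 (2.73), K10D2.8 (2.43) and jip-1 (1.63) were higher. In the descendants as a whole, 1890 features had a trend over the generations. Of 100 orders of the 9 generations that kept the libraries of a generation together, 1, the real one, gave as many, and the highest of the others gave 1421, so chance can be excluded as the source of the trend if generations are exchangeable. Neither this count nor the trend test models levels that drift while being passed from generation to generation, which would also favour the real order, so drift stays open.

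At F25, 93 features still differed from wild type, among them the pseudogene F59A1.9 and xdh-1. Whether wild-type libraries that stand apart from all descendants alike are the source stays open. Of the 93, 56.99% had a called trend within the descendants, against 21.3% of all features. The trend uses no wild-type library, but it uses the F25 libraries by which the 93 were chosen. That choice alone raises the share, so the share cannot decide. The trend of 32 features ran in the direction of their F25 difference from wild type. For 23 of them, levels left over from the meg-3/4 parents are argued against as the whole source of the F25 difference. These 23 lay beyond the meg-3/4 level at F25, such as xdh-1, aldo-1 and D2045.9 (81.1 normalized counts in wild type, 31.01 in meg-3/4, 72.5 at F3 and 461.5 at F25). For all but xdh-1 and aldo-1 the meg-3/4 level lay on the other side of wild type. A place beyond it then followed largely from the F25 call, so the count of 23 is no independent test. xdh-1 was itself called higher in meg-3/4 (13.1 normalized counts against 3.20 in wild type, limma adjusted p = 0.0369) and stood at 20.5 at F3. Leftover levels stay open for part of its rise. Most of the 23, D2045.9 included, lay on the meg-3/4 side of wild type at F3 by group means and crossed it by F25. Others are rrn-3.1, the copies of rrn-1.1 and fbxa-184 (162.8 in wild type, 9.27 in meg-3/4, 52.4 at F3 and 268.6 at F25). For features that crossed, leftover levels stay open in the early generations, and only the level past wild type at F25 is argued against. Leftover levels stay open for the other 9, of which 8 were called in the same direction in meg-3/4. Examples are fbxa-136 (log2 2.51 in meg-3/4 and 2.30 at F25) and T16H12.13 (−2.38 and −2.25). For 21 features whose trend moved toward wild type, leftover levels may be the source, since 17 of them were called in the same direction in meg-3/4, a count that the shared wild-type libraries also raise. For the other 40, with 22 called in the same direction in meg-3/4, leftover levels and wild-type libraries that stand apart cannot be told apart, because both comparisons share the 2 wild-type libraries. D2045.9 and T16H12.13 were chosen after their values were seen, and the total of 93 was 49 without wild-type replicate 1, 48 without wild-type replicate 2 and 56 without F25 replicate 2.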

How the results depend on the processing

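Equal protein-coding totals, the omission of the shallow libraries F4 replicate 2 and F10 replicate 1, and the split of the wild-type libraries were chosen after seeing the data, and the other alternatives were planned. Leaving out a library gives a group of 1, which is then assumed to vary like the other groups. Among values for the named features and lists, 314 kept their direction and side of the threshold with DESeq2 and 6 were no longer called, 318 and 2 with edgeR, 270 and 46 with equal library totals, 283 and 33 with quantile normalization, 299 and 20 with equal protein-coding totals, 255 and 65 with no filter and 318 and 2 without the shallow libraries. With 1 library left out, 3183 values kept both and 370 were no longer called, and with 1 generation left out 569 and 102. Of the 2298 features called in meg-3/4, 2294 were among those edgeR called and 2098 among those DESeq2 called. The cause of the changes given here was not tested, except where fewer features or libraries, or a stricter rule, lower a count by construction. Features with few reads are the least secure, since the libraries of F4 and F10 with the lowest depth resolve no less than 4.99 and 5.47 normalized counts. Generation as a rank or on a log2 scale did not move the trend counts by more than 1.5 times. A fit of only the groups compared was not run for the followed sets.

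A mean of at least 50, which tests fewer features, gave 805 lower in meg-3/4, totals of 956 at F3, 1088 at F4, 1012 at F5, 859 at F6, 846 at F7 and 1065 at F10, 639 lower for the descendants' mean, 508 higher in hrde-1; meg-3/4 against meg-3/4, a total of 1067 against wild type, 721 between F25 and F3 and 594 rising trends. A minimum change of log2 1 gave 301 higher in meg-3/4, totals of 933, 1072, 954, 846, 889, 1005, 334 and 113 from F3 to F20, 109 higher and 550 lower for the mean, 599 higher and 396 lower in hrde-1; meg-3/4 against meg-3/4, 684 between F25 and F3, and 609 rising and 130 falling trends. Equal library totals gave 294 higher and 2659 lower in meg-3/4, 572 at F20, 213 higher for the mean, and 1408 higher and 439 lower in hrde-1; meg-3/4 against meg-3/4. Quantile normalization gave 1390 higher in meg-3/4 and 852 higher for the mean. A fit of only the groups compared gave totals of 949 at F4, 792 at F10, 1269 at F15, 627 at F20 and 2552 for hrde-1; meg-3/4 against wild type. edgeR gave 2196 at F6, 494 at F20, 223 at F25 and 925 higher for the mean, and DESeq2 1094 at F10, 337 at F20 and 179 at F25. No filter gave 136 at F20, 313 higher for the mean and 431 falling trends, and an added count of 20 gave 426 at F20. Omitting the shallow libraries gave 1128 at F15, 580 at F20 and 172 at F25. Without generation F25, 795 trends rose and 333 fell. With an estimated correlation, 1 list passed in meg-3/4, 0 for the mean and 0 for the trend (2, 0 and 2 unadjusted).

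The medians of the gained and lost sets kept their sign in each alternative. At F3 they were 0.34 and −0.69 with a mean of at least 50, 0.58 and −0.72 with equal library totals, 0.45 and −0.84 with quantile normalization, 0.41 and −0.997 by edgeR, 0.46 and −1.11 by DESeq2, 0.42 and −0.999 with no filter, 0.43 and −1.03 with an added count of 1, 0.31 and −0.64 with an added count of 20, 0.45 and −0.89 with equal protein-coding totals and 0.35 and −0.86 without the shallow libraries. The gained median at F3 was 0.38 with a replicate block and 0.42 with no intensity trend. For hrde-1; meg-3/4 against meg-3/4 the gained and lost medians, in the order of the 10 settings, were −0.38 and 0.37, −0.67 (gained only), −0.33 and 0.50, −0.40 and 0.64, −0.52 and 0.70, −0.55 (gained only), −0.47 and 0.64, −0.39 and 0.33, −0.51 and 0.57, and −0.38 and 0.49. The gained median there was −0.44 with a replicate block and −0.53 with no intensity trend. With sets called against wild-type replicate 1 and followed against replicate 2 the medians were 0.45 and −1.05 at F3 and 0.08 and −0.24 at F25, and with the libraries exchanged 0.47 and −1.03, then 0.12 and −0.22. Features that changed by at least log2 2 in meg-3/4 had medians of 1.62 and −1.77 at F3, 0.30 (gained) at F25, and −1.81 and 0.77 in hrde-1; meg-3/4 against meg-3/4.

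Some directions reversed. With equal library totals set-32 was at −0.0170 and htp-1 at −0.0601 in meg-3/4, and sid-1 at −0.0832 in hrde-1; meg-3/4 against wild type. With quantile normalization bath-45, called higher in meg-3/4 (0.38), was called lower (−0.31, adjusted p = 0.00342, within 0.000415 to 0.939 over its alternatives), and hrde-1 was at −0.0220 for the mean. The trend of meg-4 was 0.00139 without generation F6, 0.00125 without F7, 0.00247 without F20 and 0.00927 without F25.

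With each library left out in turn, the higher count in meg-3/4 ranged from 410 to 551, and the totals from 912 to 1033 at F3, 1056 to 2332 at F4, 924 to 1084 at F5, 787 to 855 at F6, 803 to 895 at F7, 982 to 2400 at F10, 226 to 315 at F15, 61 to 101 at F20 and 48 to 75 at F25. For the mean the higher count ranged from 173 to 670 and the lower from 592 to 1508. The higher count of hrde-1; meg-3/4 against meg-3/4 ranged from 616 to 669, the total between F25 and F3 from 485 to 1014 and the falling trends from 370 to 855. meg-3 ranged from −0.0518 to 0.48 for the mean and from −0.40 to 0.60 in hrde-1; meg-3/4 against meg-3/4, sid-1 from −0.0748 to 0.11 in hrde-1; meg-3/4 against wild type, and the trend of meg-4 from −0.00688 to 0.00648. The gained and lost medians ranged from 0.38 to 0.57 and from −1.11 to −0.93 at F3, from 0.06 (without F25 replicate 2) to 0.16 and from −0.36 (without F25 replicate 1) to −0.13 (without F25 replicate 2) at F25, and from −0.79 (without meg-3/4 replicate 2) to −0.47 and from 0.53 to 0.64 in hrde-1; meg-3/4 against meg-3/4.

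The differences between replicates correlated above 0.1 in 30 of 66 pairs of groups (−0.0759 to 0.469) and in 22 of the 36 pairs of descendant groups. Replicate numbers were to be treated as pairs only if every pair exceeded it, so the fit has no replicate term. With that term the counts were 819 and 1618 in meg-3/4, 613 and 1404 for the mean, 985 and 826 in hrde-1; meg-3/4 against meg-3/4, and 1282 and 716 for the trend. The totals were 1681, 2029, 1883, 1596, 1640, 2026, 796, 317 and 136 from F3 to F25, 1711 for hrde-1; meg-3/4 against wild type and 1228 between F25 and F3.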

Other observations

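The tests of chromosomes, of features that hold microRNA reads, of differences between replicates and of ribosomal RNA genes were chosen only after the results were seen. Genes that lost small RNAs in meg-3/4 were more frequent on the X chromosome. Of 832 kept features there, 202 were lower (24.3%, against 16.9% elsewhere; odds ratio 1.58, Fisher's exact test, adjusted p = 6.8e-06 over 24 tests), and fewer were higher (5.89% against 8.54%, adjusted p = 0.0387). The excess of lower features on X stood under each scaling (35.3% against 29.4% with equal library totals, 20.2% against 14.5% with quantile normalization), while the higher shares were 3.49% and 3.31% with equal library totals. On the other chromosomes the smallest adjusted p was 0.0387. From meg-3/4 to hrde-1; meg-3/4 more X-linked features fell as well (13.2% against 8.10%, odds ratio 1.73, adjusted p = 2.9e-05). Features are not independent replicates, so these p-values describe the list of features and not the spread between animals. Of 53 small nucleolar RNA features kept, 16 were higher and 1 lower in meg-3/4, and 2 were higher and 13 lower in hrde-1; meg-3/4 than in meg-3/4 (13 and 4, then 2 and 11, with equal library totals). Of the 20 kept features that hold microRNA reads, limma called 1 higher in meg-3/4 (9 at an unadjusted p under 0.05, 4 by edgeR, 2 by DESeq2; median log2 change 0.82). In hrde-1; meg-3/4 against meg-3/4 limma called 0 (2 unadjusted), edgeR 0 (3 unadjusted) and DESeq2 0 (3 unadjusted), with a median of −0.57. All 20 lay above wild type in meg-3/4 (log2 0.36 to 1.29) and all 20 below meg-3/4 in hrde-1; meg-3/4 (−0.37 to −1.32). Their values with equal library totals are not given here, so a shared shift in scaling stays open.

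Replicate 1 and replicate 2 of the descendants differed alike in many generations. seld-1, the gene of selenophosphate synthetase, averaged 105.5 normalized counts in replicate 1 and 3413 in replicate 2 of the 9 descendant groups (log2 difference 4.96, SE 0.0636, higher in 9 of 9 groups), afmd-2 averaged 47.7 and 118.3, and cdk-14 365.1 and 92.6. Among features named for the mean of the descendants, ZC190.8 averaged 47.3 in replicate 1 and 124 in replicate 2, and aldo-1 202.9 and 110.7. Their log2 differences were 1.15 and −1.06, each with the same sign in 9 of 9 groups. Over all kept features 109 were higher and 75 lower in replicate 2. sid-1 differed by −0.03 and rde-11 by 0.40 (adjusted p = 0.0612). These genes, other than sid-1 and rde-11, were chosen after their values were seen.

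Over the 1449 features with a mean of at least 200, the differences between replicates correlated between generations with a mean r of 0.475 in 36 pairs, across features, which are not independent replicates. The correlations here are Pearson's, in which a few genes with large differences, such as seld-1, may weigh heavily. None was computed without such genes, which limits the arguments that follow. For 1253 protein-coding features a preparation shared by all libraries of a replicate number is argued against as the whole source: the wild-type, meg-3/4 and hrde-1; meg-3/4 differences correlated with the mean descendant profile at 0.0275, 0.0572 and −0.0108, a mean of 0.0246, below the lowest value of a descendant generation, 0.510, and reads of features that overlap microRNA genes are argued against by the mean between generations of 0.517. For the share of reads in F16A11.6 and K01F9.6, which hold microRNA reads, such a preparation may be the source, since replicate 1 was higher in 11 of 12 groups (15.04% against 14.4% in wild type, 25.97% against 20.05% in meg-3/4, 19.8% against 18.99% in hrde-1; meg-3/4 and 24.3% against 16.3% at F25), as were the features opposite ribosomal RNA genes in 10 of 12 (13050 against 8601 in wild type). Separate lines that carry their own small RNA levels may account for the pattern, because the correlation fell as the gap between generations grew (r = −0.523, one-sided permutation p = 0.00369, 1e+05 permutations). A batch confined to the descendants stays open, and the labels do not say whether the replicates were kept as separate lines.

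Reads antisense to ribosomal RNA genes differed between the groups. Their sum was 3298 ± 225.8 normalized counts in wild type, 8272 ± 277.4 in meg-3/4, 5254 at F3, 1482 ± 281 at F25 and 5390 ± 26.5 in hrde-1; meg-3/4 (SD, n = 2). It was taken over all 22 listed ribosomal RNA features, of which 4 were kept for testing. Ribosomal RNA fragments counted on the wrong strand are argued against for the fall over the generations, where the log2 ratio to the 3 features opposite ribosomal RNA genes ranged over 2.36 between the 9 groups (pooled SD 0.543), but may account for the differences among wild type, meg-3/4 and hrde-1; meg-3/4, where it ranged over 0.647 and the opposite features moved along (10830, 42950 and 24320). The deposited size factors are argued against for the rise in meg-3/4, since the median log2 change in meg-3/4 was 1.38 after rescaling to equal protein-coding totals. No biological explanation was tested, and differences in RNA quality stay open.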
